A study of Mus musculus with 12 samples.

How the data were processed

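The study profiled dermal fibroblasts of mouse back skin before and after wounding. Male C57BL/6 mice of 8 weeks were left unwounded (NW) or received punch wounds of 4 mm, and skin was taken 16 h, 1.5 d or 3 d later, with 3 mice per group. Per the labels, tissue was digested with liberase and passed through strainers of 70 and 40 µm, and live cells negative for CD45 and CD31 and positive for SCA1 were sorted. RNA yields were 76 to 789 ng with a mean of 375 ng, at RNA integrity numbers of at least 7. Full-length cDNA was made with a SMART-Seq v4 kit, libraries with Nextera XT from 150 pg of cDNA, and they were sequenced as paired ends on a NextSeq 500. This protocol does not keep the strand.

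The deposited values are counts of fragments per gene symbol, with no normalization. Per the file headers, the authors ran featureCounts 2.0.0 on the 12 alignments, counting read pairs over exons of a refGene annotation of mm10; no strand, multi-mapping or overlap option was set. Fragments that align to several places, or to exons of several genes, were therefore not counted, so that levels of near-identical genes (Hspa1a and Hspa1b, Krt6a and Krt6b, the Saa genes, the Ly6 genes) are uncertain. Without strand, a fragment from an antisense or overlapping gene cannot be assigned: of 128 genes named in the text, 14 share exon sequence with another gene, among them Lipe with 24.7% of its exon length, Loxl3 with 13.1%, Plod2 with 9.32%, Cd34 with 5.65% and Prg4 with 4.77%. STAR, SAMtools, Subread and Partek are named by the authors without versions. The values were checked to be whole numbers, and all 12 columns were matched to their libraries by the column names the labels give. The table holds 25239 genes and no mitochondrial ones.

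Library totals ranged from 26389453 to 43493475 counts. At that depth 3 counts stand for between 0.069 and 0.114 CPM in a library, and the floor used for a group with no counts is 3 counts over the group. Bounds and intervals from counts cover counting error only, not the spread between mice. Within groups the correlation of log2 CPM between libraries was 0.916 to 0.956, and the spread between replicates was at least 87.24 times what counting alone gives (chi-square per degree of freedom).

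Genes were filtered with filterByExpr, which left 14901, and scaled by TMM. A fit by group over all 12 libraries, with robust quasi-likelihood dispersions, was made with edgeR 4.0.16 in R 4.3.3. The 6 pairwise comparisons of the 4 groups were tested with the edgeR quasi-likelihood test and any difference among the groups with the F test over the 3 wound coefficients together. P values were adjusted by Benjamini-Hochberg over all genes tested, and a gene was called at an adjusted p under 0.05. Adjusted p values in the text are from this test unless another is named. An SE of a log2 change was not estimated directly. It was back-calculated as the size of the change over the square root of the test's F, so it is approximate. Levels are TMM-normalised CPM, and principal components were taken from log2 CPM with a prior count of 2. A fold against a group with no counts is given as a lower bound.

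Gene lists, 28 of fibroblast programmes and 10 of other cell types, were fixed before the data were examined, as were the comparisons, tests, named-gene rule and all alternatives except those said to have been chosen later. The programme lists cover chemokines and cytokines, NF-kB targets, interferon-stimulated genes, complement and acute phase, glycolysis, hypoxia, the TCA cycle, oxidative phosphorylation, fatty acid oxidation, cholesterol synthesis, serine and one-carbon metabolism, NRF2 antioxidant genes, ER stress and folding, ribosome biogenesis, immediate early genes, G1/S, G2/M, collagens, matrix glycoproteins, proteases, collagen processing, contractile genes, growth factors, Wnt pathway genes, and general, adventitial, papillary and preadipocyte fibroblast markers. The others hold markers of neutrophils, macrophages, lymphocytes, endothelium, keratinocytes, pericytes, Schwann cells and melanocytes, skeletal muscle, adipocytes and red blood cells. A few genes stand in more than 1 list, and fibroblasts express several genes of the pericyte, adipocyte and macrophage lists. Each list was tested against the other genes with camera of limma 3.58.1, with the correlation between genes preset at 0.01 and with it estimated from the data. The directional test of fry asked whether a list's members shifted together in 1 direction, without reference to other genes. Members were counted as called over all genes and as called when adjusted over the list alone.

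Genes named in the text follow a fixed rule: a panel of 18 genes; the 8 largest rises and falls against NW, or 5 between wound times, among called genes with a mean of at least 20 CPM in the higher group, groups that do not overlap and a symbol that is not a predicted gene; and up to 4 members of each list with the smallest p. Alternatives tried were DESeq2 size factors in edgeR, total counts as library sizes, DESeq2 1.42.0 (Wald test, or likelihood ratio test), limma-voom, no filter, a filter of 5 CPM in 3 libraries, a replicate block, only the 6 libraries compared, leaving out each library in turn, estimated correlation or fry for the lists, and a 2-fold minimum for the overlap of wound calls. After the marker levels per library were seen, a keratinocyte score (mean log2 CPM of that list) was added as a covariate, and genes whose deviations within groups follow the score (r over 0.7) were left out.

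The procedure was tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold per comparison, far fewer than were called against NW. It recovered 3% to 11% of genes changed 2-fold and 52% to 57% of those changed 4-fold, with 1 to 5 false calls. The chance overlap with shared controls was simulated on 40 data sets in which the wound groups did not differ from NW. No library was left out of the comparisons. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.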

Results

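RNA was sequenced from sorted fibroblasts of male C57BL/6 mouse back skin at 8 weeks of age. The sort kept live cells with surface SCA1, the product of Ly6a, and without CD45, which marks leukocytes, or CD31, which marks endothelium. Unwounded skin (NW) was compared with full-thickness punch wounds of 4 mm taken 16 h, 1.5 d and 3 d after injury. Each of the 4 groups had 3 libraries from 3 different mice. The 12 libraries held between 26389453 and 43493475 counted fragments. Replicates 1, 2 and 3 held 27407164, 28810566 and 29181224 for NW and 30601136, 31450940 and 26431358 at 16 h. They held 32277039, 38973316 and 43493475 at 1.5 d, and 27308855, 28556445 and 26389453 at 3 d. A count of 3 corresponds to between 0.069 and 0.114 CPM (counts scaled to the same library total) in a library. Below, levels are TMM-normalised CPM given as mean ± SD with n = 3 per group unless another unit is named, and coordinates are in mm10.

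The sorted cells carried the transcripts of the gate and few of the excluded types. Ly6a stood at 1053 ± 158 CPM in NW, 1514 ± 382 at 16 h, 2020 ± 781 at 1.5 d and 1091 ± 125 at 3 d. Ptprc, which encodes CD45, reached at most 9.19 CPM before TMM scaling, in replicate 2 at 16 h, and Pecam1, which encodes CD31, at most 4.11 CPM, in NW replicate 3. Keratinocyte markers were present in every library and took a larger share of counts in NW. The 18 genes of that list made up 3.18% ± 1.1 of counts in NW, 1.15% ± 0.309 at 16 h, 0.618% ± 0.171 at 1.5 d and 0.802% ± 0.699 at 3 d (SD, n = 3). Within the 3 d group this share ranged from 0.0875% in replicate 1 to 1.48% in replicate 3. The 10 most abundant genes of each library took 20.5% ± 4.51 of its counts in NW and 11.2% ± 3.13 at 16 h, 12.7% ± 1.01 at 1.5 d and 20.3% ± 4.09 at 3 d. The principal component plot set NW apart from the wounds along the component with 34.9% of the variance and ordered 16 h, 1.5 d and 3 d along the one with 16.9%. Replicate 3 at 16 h lay apart from its group on the latter axis and held the highest share of the ribosomal transcript Rn45s, 2.01% of its counts.

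**Figure D1:**
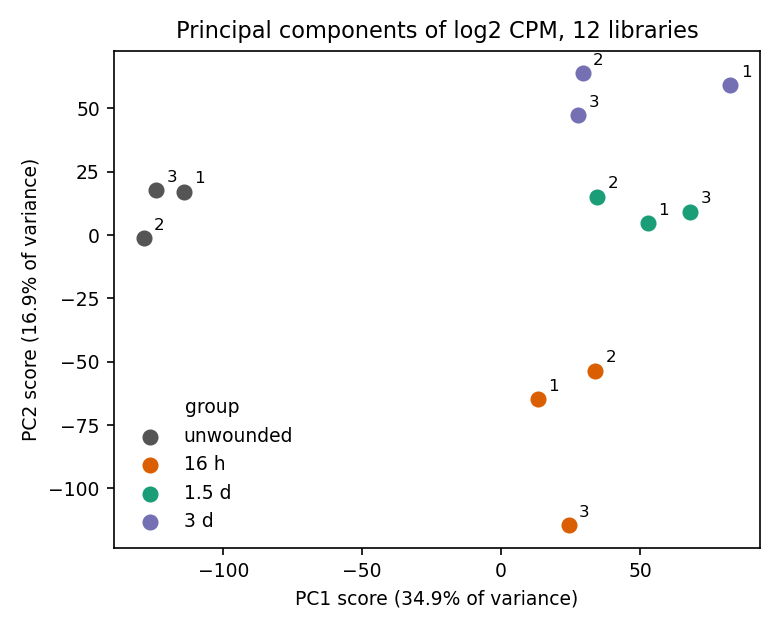
Principal component scores of the 12 libraries from log2 CPM of all tested genes; each point is 1 library, coloured by group and numbered by replicate. The 3 NW libraries sit at negative scores on the first axis (34.9% of variance) and all 9 wound libraries at positive ones, while the second axis (16.9%) separates 16 h, at the negative end, from 3 d.

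**Figure D2:**
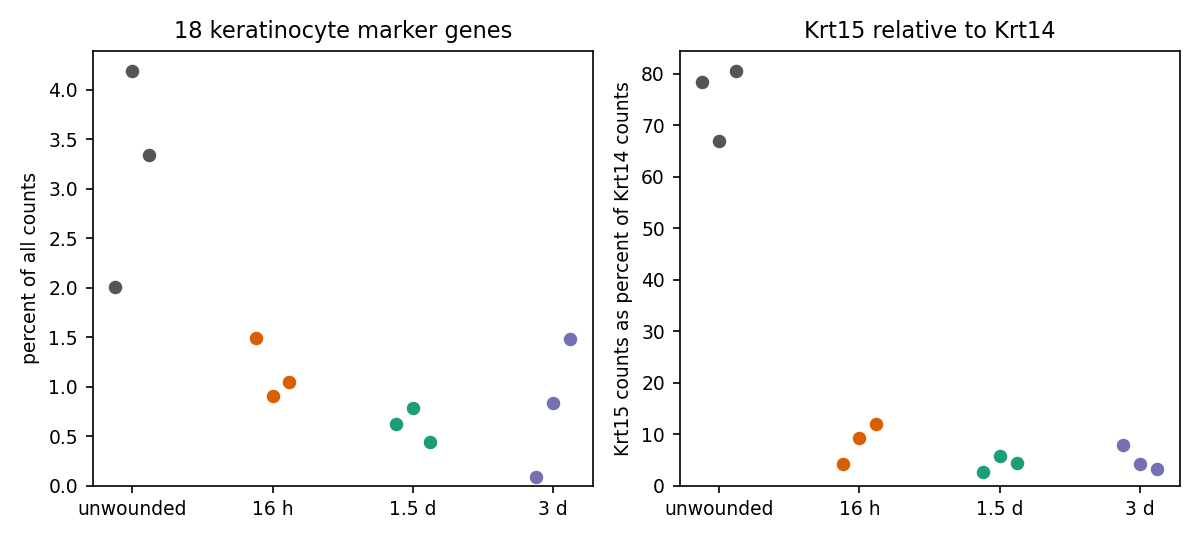
Left, counts of the 18 keratinocyte marker genes as a percent of all counts of a library; right, Krt15 counts as a percent of Krt14 counts. Each point is 1 library (n = 3 per group); the Krt15 ratio lies between 66.9% and 80.6% in NW and between 2.69% and 12% in the wounds.

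Of 25239 genes in the table, 14901 had enough counts to be tested, and 4431 of them (29.7%) differed among the 4 groups by the edgeR quasi-likelihood F test. Against NW, similar numbers of genes rose and fell at each time, whereas few genes separated 3 d from 1.5 d. The bar plot of calls gives each number. For 38 gene lists camera, with the correlation between genes preset at 0.01, called 22, 22 and 19 lists against NW at 16 h, 1.5 d and 3 d. A correlation estimated from the data left 4 list calls over the 6 comparisons: contractile genes in 3 d against each other group and ribosome biogenesis in 3 d against 16 h. Fry asks whether the members of a list shifted together in 1 direction, without setting them against other genes. It called 25, 25 and 23 lists against NW. For 1.5 d against 16 h, 3 d against 1.5 d and 3 d against 16 h camera called 16, 21 and 18 lists and fry 7, 4 and 17. Leaving out 1 library at a time moved the number that differed among groups to between 3348 and 4323.

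**Figure D3:**
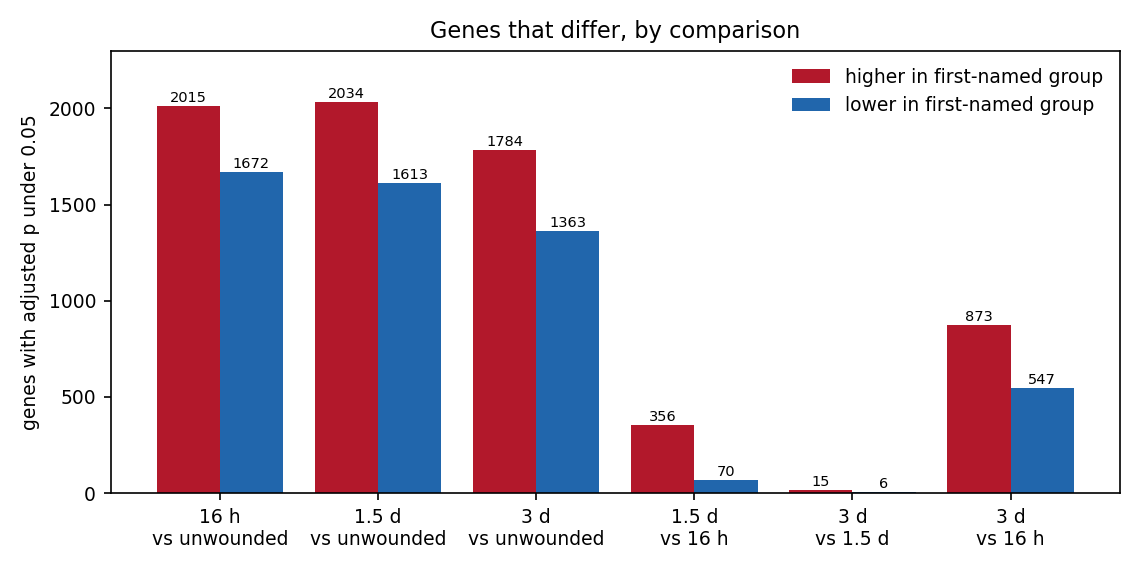
Number of genes with an edgeR adjusted p under 0.05 in each of the 6 comparisons, split into those higher (red) and lower (blue) in the first-named group, n = 3 libraries per group. The comparisons with NW call between 1363 and 2034 genes per direction, and 3 d against 1.5 d calls 15 and 6.

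The comparison of 16 h with NW asks what these fibroblasts express within the first day of injury. Some genes that were scarce in NW reached high levels. Cxcl5, a neutrophil chemokine (chromosome 5, 90759298 to 90761625), rose from 4.62 ± 4.93 to 4613 ± 667 CPM. Tnc, the matrix protein tenascin C of healing wounds (chromosome 4, 63959785 to 64047015), rose from 13 ± 3.73 to 2075 ± 1060 CPM. The acute phase gene Saa3 (chromosome 7, 46711998 to 46715676) rose from 2.76 ± 3.46 to 713.3 ± 317 CPM. The lubricating proteoglycan Prg4 (chromosome 1, 150449412 to 150466165) rose from 21.2 ± 1.71 to 1564 ± 281 CPM. In the opposite direction, Sfrp2, a secreted Wnt modulator (chromosome 3, 83766321 to 83774314), fell from 280.9 ± 71.8 to 35.6 ± 13.7 CPM. Ogn, a small leucine-rich proteoglycan, fell from 483.2 ± 210 to 55.7 ± 15 CPM. Aldh1a2, which makes retinoic acid, had no counts in NW and 23.2 ± 2.04 CPM at 16 h, at least 672-fold higher when NW is set at 3 counts over the group.

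In all, 2015 genes rose and 1672 fell at 16 h, 24.7% of those tested, and of these 1449 and 1437 changed at least 2-fold. The libraries of both groups did not overlap for 41.3% of genes, where chance gives 10%. By the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, Cxcl5 changed by 9.97 on the log2 scale (SE 0.872, adjusted p = 2.52e-05), Tnc by 7.32 (SE 0.554, adjusted p = 1.04e-05), Prg4 by 6.21 (SE 0.491, adjusted p = 1.41e-05) and Sfrp2 by -2.98 (SE 0.428, adjusted p = 0.000423). The largest falls included Smpd3, a neutral sphingomyelinase (-5.80, adjusted p = 2.6e-05 by edgeR; chromosome 8, 106252548 to 106337965), and Car3, a carbonic anhydrase abundant in fat (-7.14, adjusted p = 0.000296; chromosome 3, 14863538 to 14872373). Without replicate 2 of 16 h the counts were 1308 and 941, and with a keratinocyte marker score as a covariate, a fit chosen after the data were seen, 1151 and 788.

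Many chemokine, cytokine and interferon-stimulated genes rose at 16 h. Of 26 measured chemokines and cytokines 16 rose and 2 fell, or 18 and 4 adjusted over the list alone (median 1.68, camera adjusted p = 7.17e-10; adjusted p = 0.255 with an estimated correlation). The neutrophil chemokine Cxcl1 rose 3.35-fold to 3568 ± 756 CPM, the cytokine Il6 3.05-fold to 1186 ± 119 CPM, the alarmin Il33 11.7-fold to 2409 ± 321 CPM and the cytokine Lif 17.7-fold to 266 ± 48.5 CPM. Ccl2, a monocyte chemokine already at 1382 ± 516 CPM in NW, stood at 2292 ± 640 CPM and did not pass (edgeR adjusted p = 0.192). Among 16 complement and acute phase genes 7 rose, and the same number adjusted over the list alone (camera adjusted p = 7.46e-05; adjusted p = 0.348 with an estimated correlation), with complement factor B, Cfb, up 23.3-fold to 2419 ± 247 CPM and Ptx3, a pattern recognition protein, up 3.67-fold. Of 24 interferon-stimulated genes 12 rose, 17 with 1 fall adjusted over the list alone (camera adjusted p = 2.55e-05; adjusted p = 0.365 with an estimated correlation), among them the nucleic acid sensor Zbp1 (4.52-fold) and the antiviral gene Rsad2 (9.96-fold). NF-kB targets were mixed: 7 of 19 rose and 3 fell, 10 and 3 adjusted over the list alone (camera adjusted p = 0.0148; adjusted p = 0.39 with an estimated correlation). Sod2, a mitochondrial superoxide dismutase, rose 5.64-fold and the adhesion molecule Vcam1 4.46-fold, while the transcription factor Irf1 was 4.07-fold lower.

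Many glycolysis and ribosome biogenesis genes also rose at 16 h. Ribosome biogenesis genes were the most uniform group: 16 of 18 rose, 17 adjusted over the list alone (median 1.64, camera adjusted p = 9.87e-16; adjusted p = 0.0881 with an estimated correlation). Ncl, the nucleolar protein nucleolin, went from 367.9 ± 36.5 to 1625 ± 180 CPM, and Mybbp1a, a nucleolar regulator, and Rrp12, a ribosome assembly factor, each rose 5.11-fold. The share of counts on the ribosomal precursor Rn45s was 1.28% ± 0.723 at 16 h and 0.523% ± 0.0329 in NW. At 16 h it was 2.01% in replicate 3 but 0.5594% in replicate 2, next to 0.5589% in the highest NW library. In glycolysis, 11 of 18 genes rose and 1 fell, 13 and 2 adjusted over the list alone (camera adjusted p = 3.49e-07; adjusted p = 0.255 with an estimated correlation). Ldha, lactate dehydrogenase A, rose 4.02-fold to 1967 ± 54.4 CPM, Hk2, a hexokinase, 4.19-fold, and Pkm, pyruvate kinase, 3.91-fold. The transcript of the oxygen-regulated factor Hif1a rose 3.28-fold to 936.6 ± 293 CPM and Vegfa, an angiogenic growth factor, 6.67-fold. The 19 hypoxia-responsive genes split into 7 up and 2 down, 8 and 3 adjusted over the list alone, and did not pass as a set (camera adjusted p = 0.13). P4ha2, a collagen prolyl hydroxylase in that list, was 3.08-fold lower. Serine and one-carbon metabolism had 7 of 12 genes up and 1 down on either adjustment (camera adjusted p = 0.00154; adjusted p = 0.142 with an estimated correlation), led by Mthfd1l of the mitochondrial folate pathway (15.8-fold).

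Some antioxidant, folding and TCA cycle genes also rose at 16 h, while oxidative phosphorylation, fatty acid oxidation and cholesterol synthesis did not pass as sets. NRF2 antioxidant genes had 7 of 14 up on either adjustment, such as Gsr, glutathione reductase, 3.01-fold (camera adjusted p = 0.0148; adjusted p = 0.348 with an estimated correlation). ER stress and secretory folding genes had 9 of 18 up and 1 down, 11 and 2 adjusted over the list alone, such as the chaperone Hspa5, 2.64-fold (camera adjusted p = 0.00342; adjusted p = 0.41 with an estimated correlation). In the TCA cycle 6 of 17 rose, 7 adjusted over the list alone (camera adjusted p = 0.0148; adjusted p = 0.41 with an estimated correlation), with Dlst, of the oxoglutarate dehydrogenase complex, up 2.21-fold. Oxidative phosphorylation genes had a median of 0.00 and 2 of 24 up over all genes, neither of which passed adjusted over the list alone (camera adjusted p = 0.544). This does not show that they were unchanged. Fatty acid oxidation had 1 up and 3 down of 18 on either adjustment (camera adjusted p = 0.212), Acadm and Acaa2 being 2.17-fold and 2.12-fold lower and Acads 2.18-fold higher, each an enzyme of the pathway. Cholesterol synthesis had 2 of 18 up on either adjustment, with a median of -0.10, a mean of 0.12 and an upward sign in camera (adjusted p = 0.897).

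Many G1/S and DNA replication genes rose and many G2/M genes fell at 16 h. G1/S and DNA replication genes had 10 of 19 up and 1 down, 11 and 1 adjusted over the list alone (camera adjusted p = 2.55e-05; adjusted p = 0.295 with an estimated correlation), with the helicase subunits Mcm2 and Mcm5 up 4.07-fold and 3.76-fold. G2/M genes had 11 of 20 down, 13 adjusted over the list alone (median -1.24, camera adjusted p = 1.35e-04; adjusted p = 0.41 with an estimated correlation). Cdc20, an activator of the anaphase-promoting complex, fell from 35.7 ± 13.7 to 10 ± 4.27 CPM. Immediate early and dissociation stress genes had 13 of 18 down and 2 up, 15 and 2 adjusted over the list alone (camera adjusted p = 2.55e-05; adjusted p = 0.348 with an estimated correlation). Btg2, an antiproliferative gene, and Nr4a1, an orphan nuclear receptor, were 2.56-fold and 2.38-fold lower, and Ier3 2.86-fold higher. Keratinocyte markers took a smaller share of counts in the same libraries, 1.15% ± 0.309 against 3.18% ± 1.1 in NW.

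Falls at 16 h included Wnt pathway genes and some adventitial and preadipocyte genes, while matrix genes went both ways. Of 18 Wnt pathway genes 10 fell, 12 with 1 rise adjusted over the list alone (median -1.53, camera adjusted p = 9.05e-06; adjusted p = 0.142 with an estimated correlation), among them the ligand Wnt5a (3.17-fold lower) and Dkk3 (6.58-fold lower). Adventitial and fascia markers had 7 of 16 down and 1 up, 8 and 3 adjusted over the list alone (camera adjusted p = 0.00893; adjusted p = 0.39 with an estimated correlation). Pi16, a marker of adventitial progenitors, fell from 2045 ± 112 to 551.5 ± 144 CPM and the peptidase Dpp4 from 316.9 ± 96.6 to 67.2 ± 0.759 CPM. Preadipocyte genes had 6 of 16 down, 7 adjusted over the list alone (camera adjusted p = 0.0422; adjusted p = 0.356 with an estimated correlation), such as the apolipoprotein Apoe, 5.2-fold lower. Papillary and hair follicle fibroblast markers had 2 of 14 up and 5 down on either adjustment (camera adjusted p = 0.13), and Alpl, alkaline phosphatase, rose 44.4-fold. General fibroblast markers had 4 of 16 up and 4 down, 5 and 4 adjusted over the list alone, with a median of 0.20 and a mean of -0.18, the sign camera gave (adjusted p = 0.885). The receptor Pdgfra rose 5.02-fold to 747.5 ± 176 CPM and the surface glycoprotein Cd34 was 3.85-fold lower.

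Matrix proteases and regulators had 11 of 19 up and 3 down at 16 h, 13 and 4 adjusted over the list alone (camera adjusted p = 5.37e-04; adjusted p = 0.278 with an estimated correlation). Timp1, a protease inhibitor, rose 30-fold, Mmp3, stromelysin, rose 3.61-fold to 3514 ± 490 CPM, and Timp3 was 5.34-fold lower. The 15 collagen genes split evenly, 4 up and 4 down, or 4 and 5 adjusted over the list alone, with a median of -0.37, a mean of 0.18 and a downward sign in camera (adjusted p = 0.902). Col8a1, a short-chain collagen, rose 16.7-fold and Col5a1 was 2.76-fold lower. Col1a1, the main fibrillar collagen, stood at 15380 ± 11700 CPM against 42150 ± 19000 in NW (edgeR adjusted p = 0.0645). DESeq2 called Col1a1 at adjusted p = 0.0105 and limma-voom at 0.0293. EdgeR did so with total-count scaling at 0.0439, with the stricter CPM filter at 0.0495, and without replicate 2 of NW or replicate 1 of 16 h at 0.038 and 0.0112. Matrix glycoproteins had 3 of 21 up and 6 down, 4 and 7 adjusted over the list alone, with a median of -0.50, a mean of 0.01 and a downward sign in camera (adjusted p = 0.604). Collagen processing genes had 5 of 15 up and 3 down, 6 and 5 adjusted over the list alone (camera adjusted p = 0.159), with the lysyl hydroxylase Plod2 up 17.4-fold. Contractile genes had 4 of 15 up and 5 down on either adjustment, with a median of -0.58 and an upward sign in camera (adjusted p = 0.885). The actin crosslinker Actn1 rose 7.29-fold and the myosin light chain Myl9 was 6.48-fold lower. Growth factors had 6 of 22 up and 5 down, 7 and 5 adjusted over the list alone (camera adjusted p = 0.595), with Fgf7, an epithelial mitogen, up 3.6-fold and Bmp4 7.25-fold lower.

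Lists of other cell types were measured beside the fibroblast groups. At 16 h mature adipocyte markers had 7 of 10 down, 7 with 1 rise adjusted over the list alone (median -3.33, camera adjusted p = 0.00148; adjusted p = 0.278 with an estimated correlation). Pericyte and vascular smooth muscle markers had 6 of 11 down and 1 up on either adjustment (median -2.16, camera adjusted p = 3.01e-04; adjusted p = 0.142 with an estimated correlation), such as the channel gene Kcnj8, 11.5-fold lower. Keratinocyte markers had 5 of 18 down and 1 up, 9 and 1 adjusted over the list alone (camera adjusted p = 0.00154; adjusted p = 0.544 with an estimated correlation). Neutrophil markers had 6 of 9 up and 1 down, 7 and 1 adjusted over the list alone, with a median of 5.31, or 4.16 with genes of an all-zero group at their bound (camera adjusted p = 0.0324; adjusted p = 0.278 with an estimated correlation). Most stayed scarce, such as the neutrophil gene S100a9 at 3.08 ± 1.09 CPM and the chemokine receptor Cxcr2 at 8.82 ± 5.4 CPM, at least 255-fold over 3 counts in NW. The decoy receptor Il1r2 of the same list was abundant and fell from 587.6 ± 142 to 121.8 ± 33.5 CPM. Macrophage and monocyte markers had 6 of 19 up and 2 down, 9 and 2 adjusted over the list alone (camera adjusted p = 0.0175, and 0.41 with an estimated correlation). The summed CPM of this list before TMM scaling overlapped with NW (72.9 to 138.4) at 16 h (71.1 to 150.1), 1.5 d (92.5 to 138.5) and 3 d (91.6 to 133.4). Endothelial markers had 3 of 13 down on either adjustment (camera adjusted p = 0.0592), Schwann and melanocyte markers 3 of 8 down and 1 up on either adjustment (camera adjusted p = 0.119), and skeletal muscle markers 1 of 11 down, not called adjusted over the list alone (camera adjusted p = 0.159). By edgeR none of 4 lymphocyte markers (camera adjusted p = 0.599) and not the 1 red blood cell marker measured (log2 change -2.55) passed.

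**Figure D4:**
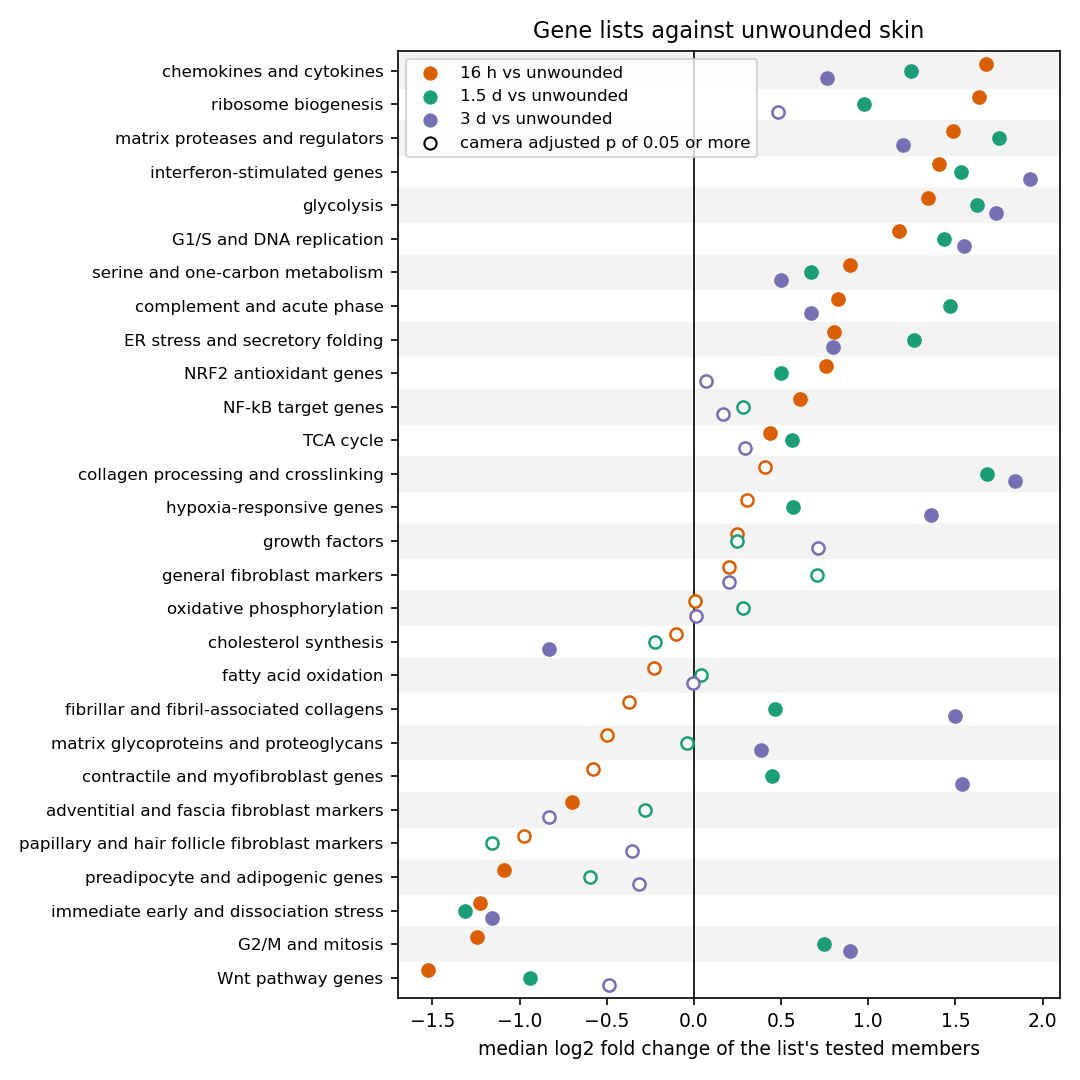
Median log2 fold change against NW of the tested members of 28 gene lists at 16 h, 1.5 d and 3 d; filled points have a camera adjusted p under 0.05 with the correlation preset at 0.01, open points do not. Ribosome biogenesis runs from 1.64 at 16 h down to 0.48 at 3 d, and the collagens from -0.37 up to 1.50.

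**Figure D5:**
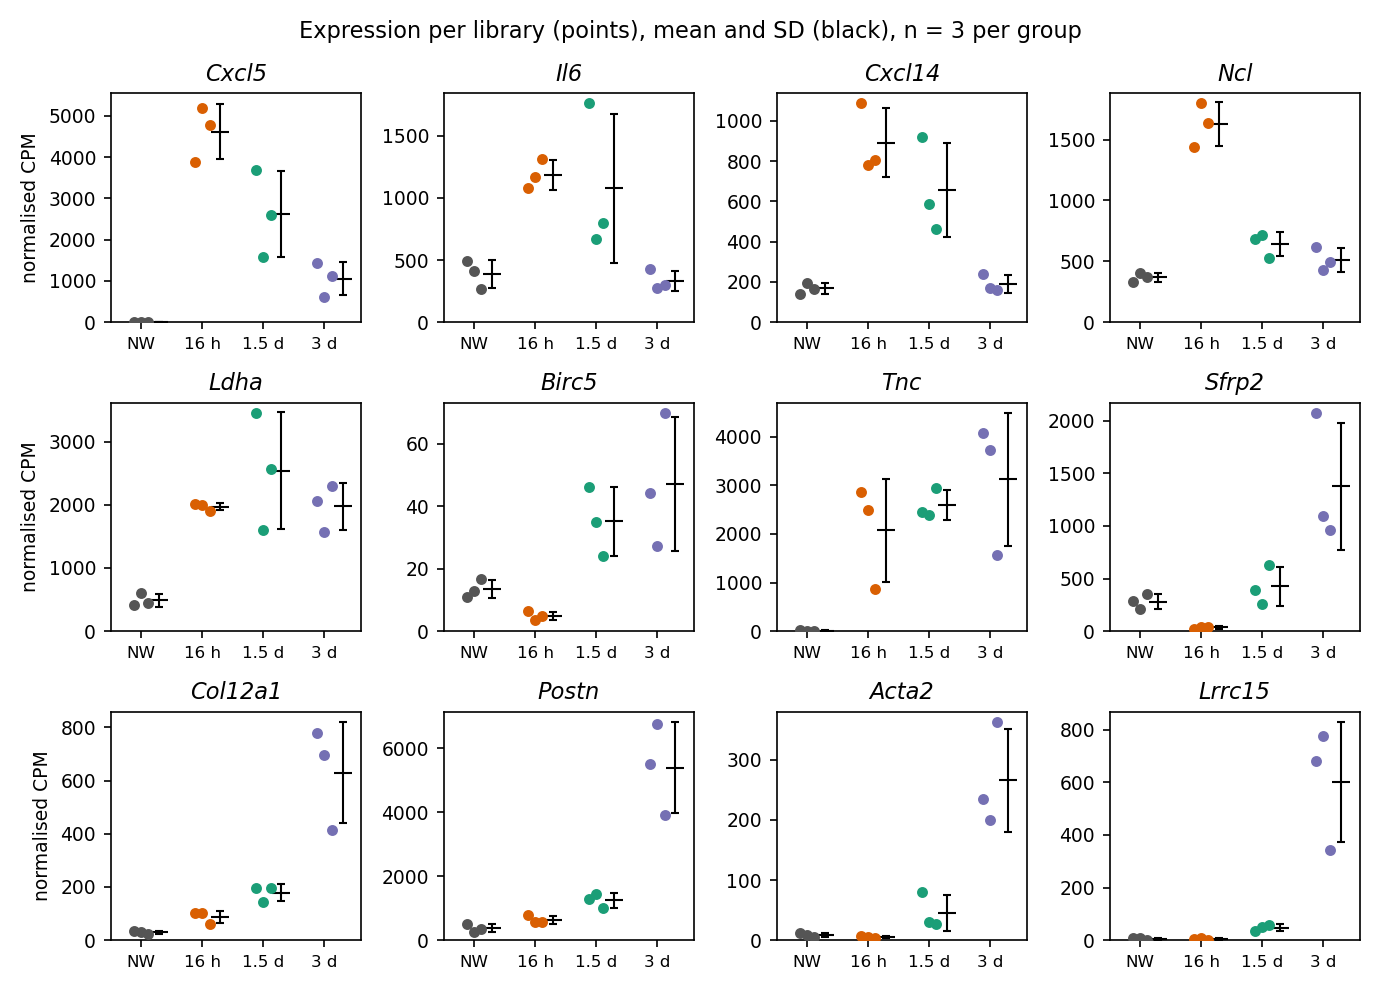
Normalised CPM of 12 genes per library (coloured points) with the group mean and SD in black, n = 3 per group, linear axes from 0. Cxcl5, Il6, Cxcl14 and Ncl are highest at 16 h, whereas Postn, Acta2 and Lrrc15 reach 5394, 265.5 and 599.7 CPM at 3 d.

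The comparison of 1.5 d with NW asks which changes were in place once the wound was more than a day old. Saa3 reached 2808 ± 1770 CPM at 1.5 d, with libraries far apart, and Cxcl5 was at 2626 ± 1050 CPM. Tnc was at 2599 ± 304 CPM, and Steap1, a metalloreductase, rose 160-fold. Il11, a profibrotic cytokine, rose from 1.11 ± 0.626 to 68.7 ± 38.2 CPM and Inhba, the activin A subunit, from 13.5 ± 11.3 to 313.9 ± 211 CPM. Acta2, the smooth muscle actin of myofibroblasts (chromosome 19, 34240336 to 34255373), rose from 8.53 ± 2.88 to 45.7 ± 29.7 CPM. Postn, the matricellular protein periostin (chromosome 3, 54359267 to 54391041), rose from 367.1 ± 123 to 1243 ± 230 CPM. The basal keratin Krt15 (chromosome 11, 100131759 to 100135949) fell from 5232 ± 1160 to 127.3 ± 69.6 CPM.

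At 1.5 d 2034 genes rose and 1613 fell, 24.5% of those tested, with 1501 and 1343 changing at least 2-fold; 40.7% of genes did not overlap, against 10% by chance. In the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, Saa3 changed by 10.01 on the log2 scale (SE 1.03, adjusted p = 4.89e-05), Acta2 by 2.42 (SE 0.443, adjusted p = 0.002), Postn by 1.76 (SE 0.293, adjusted p = 0.00118) and Krt15 by -5.36 (SE 0.635, adjusted p = 0.000131). The keratinocyte covariate, chosen after the data were seen, left 440 and 175 genes at 1.5 d, the largest drop among the comparisons with NW. Without replicate 3 of 1.5 d 961 genes fell.

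Many chemokine, complement and interferon-stimulated genes were higher than in NW at 1.5 d. Chemokines and cytokines had 15 of 26 up and 2 down, 15 and 3 adjusted over the list alone (camera adjusted p = 1.48e-07; adjusted p = 0.235 with an estimated correlation). Cxcl3 was 17.6-fold and Il33 10.3-fold higher. Il6, at 1077 ± 599 CPM, and Cxcl1, at 2657 ± 896 CPM, passed in the fit by group, at edgeR adjusted p of 0.00885 and 0.00717, but not with the keratinocyte covariate, at adjusted p of 0.252 and 0.181. Their log2 changes went from 1.47 and 1.32 to 1.01 and 1.08 with it. Of 16 complement and acute phase genes 9 rose on either adjustment (camera adjusted p = 4.26e-07; adjusted p = 0.201 with an estimated correlation), Lcn2, the siderophore-binding lipocalin, from 2.11 ± 1.58 to 293.8 ± 119 CPM. Interferon-stimulated genes had 14 of 24 up, 15 adjusted over the list alone (camera adjusted p = 3.92e-06; adjusted p = 0.272 with an estimated correlation). Zbp1 rose 7.33-fold. NF-kB targets had 6 of 19 up and 4 down, 7 and 4 adjusted over the list alone (camera adjusted p = 0.253), with Vcam1 6.69-fold higher and Irf1 4.55-fold lower. Macrophage and monocyte markers had 6 of 19 up and 1 down on either adjustment (camera adjusted p = 0.0356; adjusted p = 0.43 with an estimated correlation). Neutrophil markers had 3 of 9 up and 1 down, 6 and 1 adjusted over the list alone (camera adjusted p = 0.0554).

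Most glycolysis, G1/S and collagen processing genes rose at 1.5 d. In glycolysis 14 of 18 genes rose and 1 fell on either adjustment (camera adjusted p = 1.75e-11; adjusted p = 0.201 with an estimated correlation). The lactate exporter Slc16a3 rose from 11.2 ± 3.12 to 182.6 ± 87.9 CPM, Ldha 5.18-fold and Pkm 4.82-fold. Hypoxia-responsive genes had 6 of 19 up and 1 down on either adjustment (camera adjusted p = 0.0124; adjusted p = 0.43 with an estimated correlation). Vegfa was 4.83-fold higher. G1/S genes had 16 of 19 up and 1 down, 17 and 1 adjusted over the list alone (camera adjusted p = 4.55e-09; adjusted p = 0.201 with an estimated correlation). Mcm5 was 5.84-fold higher. G2/M genes had 5 of 20 up, 6 adjusted over the list alone (camera adjusted p = 0.0111; adjusted p = 0.529 with an estimated correlation). The mitotic kinase Plk1 was 5.36-fold higher. In collagen processing 10 of 15 rose, 11 with 1 fall adjusted over the list alone (camera adjusted p = 3.33e-09; adjusted p = 0.201 with an estimated correlation). Plod2 rose from 2.51 ± 2 to 120.7 ± 45.1 CPM and the lysyl oxidase Loxl3 13.3-fold. Ribosome biogenesis had 11 of 18 up on either adjustment (camera adjusted p = 1.82e-05; adjusted p = 0.201 with an estimated correlation). ER folding genes had 11 up and 1 down of 18 on either adjustment (camera adjusted p = 5.06e-05; adjusted p = 0.272 with an estimated correlation). The chaperone Pdia4 was 4.11-fold higher.

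Among the remaining groups at 1.5 d, immediate early genes had 16 of 18 down and 1 up on either adjustment (camera adjusted p = 4.55e-09; adjusted p = 0.201 with an estimated correlation). Zfp36, which promotes mRNA decay, fell from 1972 ± 105 to 554.5 ± 159 CPM and the heat shock gene Hspa1a, near-identical to Hspa1b, from 220.9 ± 73.8 to 41.8 ± 8.56 CPM. With the keratinocyte covariate 29.4% of this list's calls were kept, against 16.4% over all genes, and the median of the called members went from -1.34 to -1.15. Keratinocyte markers had 12 of 18 down and 1 up, 14 and 1 adjusted over the list alone (median -2.56, camera adjusted p = 1.36e-07; adjusted p = 0.325 with an estimated correlation). Their share of counts was 0.618% ± 0.171. Proteases and regulators had 13 of 19 up and 2 down, 13 and 3 adjusted over the list alone (camera adjusted p = 1.82e-05; adjusted p = 0.201 with an estimated correlation). Collagens had 5 of 15 up and 2 down, 5 and 3 adjusted over the list alone (camera adjusted p = 0.015; adjusted p = 0.529 with an estimated correlation). Col12a1, a fibril-associated collagen, was 6.07-fold higher. Matrix glycoproteins had 9 of 21 up and 3 down, 9 and 4 adjusted over the list alone, with a median of -0.04, a mean of 0.53 and an upward sign in camera (adjusted p = 0.14). Contractile genes had 6 of 15 up, 6 with 1 fall adjusted over the list alone (camera adjusted p = 0.0111; adjusted p = 0.201 with an estimated correlation). Wnt pathway genes had 8 of 18 down and 1 up, 9 and 1 adjusted over the list alone (camera adjusted p = 0.00451; adjusted p = 0.235 with an estimated correlation). Wnt5a was 3.61-fold lower. Pericyte and vascular smooth muscle markers had 3 of 11 down and 1 up, 4 and 1 adjusted over the list alone (median -1.44, camera adjusted p = 0.012; adjusted p = 0.201 with an estimated correlation). The TCA cycle had 5 of 17 up on either adjustment (camera adjusted p = 0.0115; adjusted p = 0.377 with an estimated correlation). Serine and one-carbon metabolism had 5 of 12 up and 1 down, 7 and 1 adjusted over the list alone (camera adjusted p = 0.0124; adjusted p = 0.201 with an estimated correlation). NRF2 antioxidant genes had 5 of 14 up on either adjustment (camera adjusted p = 0.0155; adjusted p = 0.3 with an estimated correlation). Mature adipocyte markers had 6 of 10 down, 7 adjusted over the list alone (camera adjusted p = 0.00143; adjusted p = 0.235 with an estimated correlation).

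The comparison of 3 d with NW asks how far the cells had moved toward matrix production. Postn rose 14.7-fold to 5394 ± 1430 CPM and Acta2 31.2-fold to 265.5 ± 85.6 CPM. Col11a1, a minor fibrillar collagen (chromosome 3, 114030540 to 114220756), and Col24a1, another fibrillar collagen, had no counts in NW and stood at 20.8 ± 6.05 and 26.2 ± 8.03 CPM, at least 602-fold and 757-fold higher over 3 counts in the NW group. The neuropeptide receptor gene Prokr2, also without counts in NW, reached 31.2 ± 22.7 CPM, at least 903-fold higher, and Ereg, the EGF family ligand epiregulin, went from 0.796 ± 1.38 to 179.5 ± 71.5 CPM. Tnc was at 3122 ± 1360 CPM, and Cxcl5 at 1057 ± 408 CPM was still 230-fold over NW.

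At 3 d 1784 genes rose and 1363 fell, 21.1% of those tested, with 1389 and 1139 changing at least 2-fold; 40.3% of genes did not overlap, against 10% by chance. In the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, Postn changed by 3.88 on the log2 scale (SE 0.32, adjusted p = 1.28e-05), Acta2 by 4.96 (SE 0.494, adjusted p = 3.62e-05) and Ereg by 7.79 (SE 1.19, adjusted p = 0.000738). The counts were 1093 and 733 without replicate 1 of 3 d, and 861 genes fell without replicate 2 of NW; the keratinocyte covariate, chosen after the data were seen, left 603 and 196. Scaling by total counts alone took the median log2 change over all genes from 0.0021 to -0.111 and turned the share of calls that were higher from 56.7% to 48.3%.

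Many collagen, collagen processing and contractile genes rose at 3 d. Of 15 collagens 11 rose, 11 with 1 fall adjusted over the list alone (median 1.50, camera adjusted p = 3.08e-10; adjusted p = 0.229 with an estimated correlation). Col12a1 rose 21.5-fold to 629.9 ± 190 CPM, Col8a1 17.8-fold, Col5a3 10.3-fold and Col6a3 5.48-fold. Col1a1 stood at 42070 ± 16300 CPM, with a log2 difference from NW of -0.00 (edgeR adjusted p = 0.998). Collagen processing had 11 of 15 up, 12 adjusted over the list alone (camera adjusted p = 7.22e-14; adjusted p = 0.213 with an estimated correlation). Plod2 was 94.7-fold and P3h1, a collagen prolyl hydroxylase, 3.86-fold higher. Contractile genes had 9 of 15 up, 11 with 1 fall adjusted over the list alone (median 1.54, camera adjusted p = 8.09e-08), and this call held at adjusted p = 0.0382 with an estimated correlation. Actn1 rose 11.9-fold and the tropomyosin Tpm4 2.52-fold. Matrix glycoproteins had 8 of 21 up and 2 down, 8 and 3 adjusted over the list alone (camera adjusted p = 0.00117; adjusted p = 0.482 with an estimated correlation). The proteoglycan Bgn was 3.69-fold and Fbln2, an elastic fibre protein, 5.86-fold higher. Proteases and regulators had 10 of 19 up and 2 down, 11 and 3 adjusted over the list alone (camera adjusted p = 2.68e-05; adjusted p = 0.213 with an estimated correlation). Timp1 was 26-fold higher.

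Most glycolysis and G1/S genes were higher than in NW at 3 d and some cholesterol synthesis genes fell. Glycolysis had 15 of 18 genes up on either adjustment (median 1.73, camera adjusted p = 9.28e-16; adjusted p = 0.105 with an estimated correlation). Slc16a3 was 28.5-fold, Pkm 5.18-fold and the enolase Eno1 5.09-fold higher. Hypoxia-responsive genes had 11 of 19 up and 1 down on either adjustment (camera adjusted p = 1.41e-05; adjusted p = 0.257 with an estimated correlation). P4ha1, a collagen prolyl hydroxylase, was 3.05-fold and the stress gene Ddit4 4.87-fold higher. Cholesterol synthesis had 8 of 18 down, 10 adjusted over the list alone (camera adjusted p = 6.83e-05; adjusted p = 0.276 with an estimated correlation). Hmgcs1, which makes HMG-CoA, fell from 235.4 ± 19 to 93 ± 7.6 CPM and the sterol enzyme Msmo1 from 82.2 ± 22.7 to 21.4 ± 5.08 CPM. With the keratinocyte covariate 37.5% of the cholesterol synthesis calls were kept, against 24.6% over all genes, and the median of the called members went from -1.33 (SE 0.286) to -1.13 (SE 0.383). Mature adipocyte markers had 5 of 10 down, 6 adjusted over the list alone (median -2.67, camera adjusted p = 2.32e-04; adjusted p = 0.229 with an estimated correlation). G1/S genes had 15 of 19 up, 17 with 1 fall adjusted over the list alone (camera adjusted p = 3.9e-10; adjusted p = 0.213 with an estimated correlation). G2/M genes had 7 of 20 up on either adjustment (camera adjusted p = 8.3e-04; adjusted p = 0.552 with an estimated correlation). Plk1 was 7.05-fold and the chromosomal passenger gene Birc5 (chromosome 11, 117849237 to 117855743) 3.50-fold higher. ER stress and secretory folding genes had 8 of 18 up and 1 down, 8 and 2 adjusted over the list alone (camera adjusted p = 0.00756, and 0.536 with an estimated correlation). Serine and one-carbon metabolism had 4 of 12 up and 1 down, 5 and 1 adjusted over the list alone (camera adjusted p = 0.0418, and 0.229 with an estimated correlation). Ribosome biogenesis had 4 of 18 up on either adjustment and did not pass as a set (camera adjusted p = 0.11), nor did the TCA cycle with 2 of 17 up on either adjustment (camera adjusted p = 0.202) or NRF2 antioxidant genes with 2 of 14 up and 1 down on either adjustment (camera adjusted p = 0.832).

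Called interferon-stimulated, chemokine and complement genes mostly rose at 3 d, while called adventitial markers mostly fell. Of 16 complement and acute phase genes 5 rose on either adjustment (camera adjusted p = 2.83e-04, and 0.3975 with an estimated correlation). Interferon-stimulated genes had 16 of 24 up, 18 adjusted over the list alone (median 1.93, camera adjusted p = 8.79e-10; adjusted p = 0.229 with an estimated correlation). Rsad2 was 14.3-fold higher. Chemokines and cytokines had 11 of 26 up and 2 down on either adjustment (camera adjusted p = 1.59e-04; adjusted p = 0.417 with an estimated correlation). Il6 was back at 333.2 ± 81 CPM against 389.3 ± 112 in NW. Macrophage and monocyte markers had 6 of 19 up and 1 down on either adjustment (camera adjusted p = 0.0167; adjusted p = 0.482 with an estimated correlation). Neutrophil markers had 1 of 9 up and 1 down, 4 and 1 adjusted over the list alone (camera adjusted p = 0.395). Immediate early genes had 14 of 18 down and 1 up, 15 and 1 adjusted over the list alone (camera adjusted p = 8.79e-10; adjusted p = 0.213 with an estimated correlation). With the keratinocyte covariate 26.7% of these calls were kept, against 24.6% over all genes, and the median of the called members went from -1.43 to -1.03. Nr4a1 was 3.26-fold lower. Pi16 was 2.75-fold lower and Cd55, a complement regulator on adventitial cells, 3.31-fold lower, while Ccn3, a matricellular protein in the same list (chromosome 15, 54745910 to 54753761), rose 10.4-fold to 207.4 ± 60 CPM. The adventitial list had 6 of 16 down and 1 up, 9 and 1 adjusted over the list alone (camera adjusted p = 0.0989). Keratinocyte markers had 10 of 18 down and 1 up, 12 and 1 adjusted over the list alone (median -2.09, camera adjusted p = 6.98e-07; adjusted p = 0.417 with an estimated correlation). The one that rose was Krt6a, a keratin of wounded epidermis near-identical to Krt6b, 18.1-fold.

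The comparison of 1.5 d with 16 h asks what changed between the first day and the second. Mitotic and collagen processing genes were among the rises and some nucleolar genes among the falls. Ccnb2, a mitotic cyclin, rose from 7.03 ± 2.63 to 63 ± 4.36 CPM and Birc5 from 4.95 ± 1.3 to 35.2 ± 11.1 CPM. Lrrc17, a secreted leucine-rich repeat protein (chromosome 5, 21543527 to 21575902), rose from 13.3 ± 3.18 to 191.5 ± 32.4 CPM and Sfrp2 from 35.6 ± 13.7 to 424.5 ± 189 CPM. Ncl fell from 1625 ± 180 to 641.1 ± 99.5 CPM, and Il31ra, a cytokine receptor (chromosome 13, 112522807 to 112580662), from 65.9 ± 22.5 to 19 ± 4.74 CPM.

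Of the tested genes 356 rose and 70 fell from 16 h to 1.5 d, 2.86%, of which 316 and 42 changed at least 2-fold; 23.4% did not overlap, against 10% by chance. In the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, Lrrc17 changed by 3.84 on the log2 scale (SE 0.244, adjusted p = 9.12e-06), Sfrp2 by 3.58 (SE 0.44, adjusted p = 0.00161), Ccnb2 by 3.16 (SE 0.411, adjusted p = 0.00212) and Ncl by -1.34 (SE 0.211, adjusted p = 0.006). G2/M genes had 13 of 20 up, 18 adjusted over the list alone (median 2.02, camera adjusted p = 2.48e-25; adjusted p = 0.121 with an estimated correlation). Aurkb, a mitotic kinase, rose 4.44-fold. Collagen processing had 9 of 15 up, 13 adjusted over the list alone (camera adjusted p = 6.34e-15; adjusted p = 0.161 with an estimated correlation). Loxl3 was 2.58-fold higher. Ribosome biogenesis had 4 of 18 down, 8 adjusted over the list alone (camera adjusted p = 5.49e-10; adjusted p = 0.121 with an estimated correlation). Contractile genes had 4 of 15 up, 5 adjusted over the list alone (camera adjusted p = 1.57e-04; adjusted p = 0.121 with an estimated correlation). Acta2 was 8.67-fold higher. Both counts were lower without any 1 of the libraries compared, a fit with a group of 2, so the drop does not single out a library. They were 164 and 11, 137 and 10, and 196 and 35 without replicates 1, 2 and 3 of 16 h. They were 227 and 36 without replicate 1 and 202 and 16 without replicate 3 of 1.5 d, and 44 genes fell without replicate 2 of 1.5 d. The keratinocyte covariate, chosen after the data were seen, left 225 and 35, and a replicate block 193 and 18.

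The comparison of 3 d with 1.5 d asks what came last in the series. Few genes passed, and those that rose include genes of matrix and myofibroblast proteins. Tnn, the matrix protein tenascin N (chromosome 1, 160085032 to 160153575), rose from 13 ± 1.44 to 134.7 ± 49.8 CPM and Ccn3 from 25.9 ± 3.13 to 207.4 ± 60 CPM. Both calls held without each library in turn. Lrrc15, a membrane protein of myofibroblasts (chromosome 16, 30269302 to 30283254), stood at 599.7 ± 228 against 47.7 ± 12.2 CPM, Postn at 5394 ± 1430 against 1243 ± 230 CPM and Acta2 at 265.5 ± 85.6 against 45.7 ± 29.7 CPM. Those 3 calls, at edgeR adjusted p of 0.0327, 0.0165 and 0.0457, ended without single libraries. Lrrc15 had adjusted p = 0.157, 0.0991 and 0.137 without replicates 1, 2 and 3 of 1.5 d and 0.0661 and 0.145 without replicates 1 and 2 of 3 d. Postn had adjusted p = 0.0508 and 0.0863 without replicates 1 and 3 of 1.5 d and 0.116 without replicate 2 of 3 d, and Acta2 had 0.124 and 0.167 without replicates 2 and 3 of 1.5 d and 0.0661, 0.119 and 0.13 without replicates 1, 2 and 3 of 3 d. Lrrc15 also missed the threshold with no filter (adjusted p = 0.0597), and Acta2 with only the 6 libraries compared (0.0784).

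In all 15 genes rose and 6 fell from 1.5 d to 3 d, 0.141% of those tested, and 1191 had an unadjusted p under 0.05; 13.6% of genes did not overlap, against 10% by chance. By the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, Tnn changed by 3.37 on the log2 scale (SE 0.36, adjusted p = 0.00256) and Ccn3 by 3.00 (SE 0.244, adjusted p = 2e-04). Adjusted over the list alone 11 of 15 collagens rose, against 1 over all genes (median 1.01, camera adjusted p = 1.17e-18; adjusted p = 0.0889 with an estimated correlation). Contractile genes had 1 of 15 up, 6 adjusted over the list alone (median 0.97, camera adjusted p = 1.85e-08), a call that held at adjusted p = 0.0154 with an estimated correlation. Of 11 pericyte and vascular smooth muscle markers 3 rose adjusted over the list alone but not over all genes (median 1.40, camera adjusted p = 7.58e-06; adjusted p = 0.0852 with an estimated correlation). Chemokines and cytokines had 1 of 26 down, the epithelial chemokine Cxcl14 (adjusted p = 0.0239 by edgeR, but 0.0661, 0.145 and 0.106 without replicate 1 of 1.5 d and replicates 2 and 3 of 3 d, and 0.0862 with only the 6 libraries compared), and 5 down and 2 up adjusted over the list alone (camera adjusted p = 7.58e-06; adjusted p = 0.393 with an estimated correlation). The calls depended on the tool and on single libraries. Limma-voom gave 52 and 22 and DESeq2 124 and 76. Without replicate 1 of 1.5 d they were 8 and 3 and without replicate 2 of 3 d 2 and 0 (773 genes at an unadjusted p under 0.05 by edgeR, with limma-voom and DESeq2 run on all libraries only). By edgeR 2 and 8 genes rose without replicate 3 of 1.5 d and replicate 1 of 3 d, and 14 and 2 fell without replicate 2 of 1.5 d and replicate 3 of 3 d. Total-count scaling gave 30 genes that fell and a share of calls that were higher of 41.2% instead of 71.4%.

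The comparison of 3 d with 16 h tests the difference between the first and last wound times directly. Many collagen, contractile and mitotic genes were higher at 3 d and many nucleolar genes lower, with some chemokine and sterol genes. Lrrc15 was at 599.7 ± 228 against 5.44 ± 3.69 CPM, Sfrp2 at 1374 ± 605 against 35.6 ± 13.7 CPM, and the imprinted noncoding RNA H19 (chromosome 7, 142575530 to 142578146) at 39.3 ± 8.32 against 0.0846 ± 0.0736 CPM. Col5a1 was at 4217 ± 1290 against 574.3 ± 169 CPM and Tgfb3, a TGF-beta ligand, at 104.1 ± 25.7 against 10 ± 1.26 CPM. Il6 was 3.56-fold lower at 3 d, Cxcl14 4.67-fold lower and Il31ra 17.7-fold lower, while the interferon-induced chemokines Cxcl9 and Cxcl10 were 19.6-fold and 4.33-fold higher.

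At 3 d 873 genes were higher than at 16 h and 547 lower, 9.53% of those tested, with 762 and 331 changing at least 2-fold; 32.5% did not overlap, against 10% by chance. In the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, Sfrp2 differed by 5.27 on the log2 scale (SE 0.476, adjusted p = 5.51e-05), Lrrc15 by 6.78 (SE 0.7, adjusted p = 0.000132), Acta2 by 5.66 (SE 0.511, adjusted p = 5.51e-05) and Il31ra by -4.15 (SE 0.331, adjusted p = 2.88e-05). Total-count scaling, with a median log2 difference over all genes of -0.189 against -0.0195 with TMM, gave 971 lower genes and a share of calls that were higher of 42% instead of 61.5%, and a replicate block gave 333 lower genes. Without a single library the counts were 523 and 203 (replicate 2 of 16 h), 549 and 268 (replicate 1 of 3 d) and 554 and 258 (replicate 2 of 3 d). By edgeR 288, 331 and 323 genes were lower without replicates 1 and 3 of 16 h and replicate 3 of 3 d.

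A pair of the list calls between 3 d and 16 h held with an estimated correlation. Ribosome biogenesis had 13 of 18 genes lower at 3 d, 18 adjusted over the list alone (median -1.17, camera adjusted p = 1.92e-17; adjusted p = 0.0322 with an estimated correlation). Rrp12 was 3.44-fold and Ncl 3.16-fold lower. Contractile genes had 9 of 15 higher, 11 adjusted over the list alone (median 1.66, camera adjusted p = 5.54e-10; adjusted p = 0.0152 with an estimated correlation). Myl9 was 15-fold and the integrin Itga11 9.12-fold higher. G2/M genes had 17 of 20 higher, 20 adjusted over the list alone (camera adjusted p = 1.18e-19; adjusted p = 0.102 with an estimated correlation). Birc5 was 9.53-fold and Ccnb2 8.96-fold higher. Collagens had 11 of 15 higher, 13 adjusted over the list alone (camera adjusted p = 1.92e-17; adjusted p = 0.102 with an estimated correlation). Col12a1 was 7.16-fold and Col5a2 4.06-fold higher. Collagen processing had 12 of 15, 14 adjusted over the list alone (camera adjusted p = 1.35e-15; adjusted p = 0.102 with an estimated correlation). The lysyl oxidase Loxl2 was 4.31-fold higher. Wnt pathway genes had 6 of 18 higher, 9 adjusted over the list alone (camera adjusted p = 8.65e-07; adjusted p = 0.0869 with an estimated correlation). Dkk3 was 6.95-fold higher. Cholesterol synthesis had 8 of 18 lower, 13 adjusted over the list alone (camera adjusted p = 1.85e-07; adjusted p = 0.206 with an estimated correlation). Msmo1 was 2.96-fold lower. Chemokines and cytokines had 9 of 26 lower and 2 higher, 13 and 2 adjusted over the list alone (camera adjusted p = 1.32e-04; adjusted p = 0.364 with an estimated correlation). Markers of pericytes and vascular smooth muscle were higher in the same comparison, 4 of 11, 6 adjusted over the list alone (median 2.15, camera adjusted p = 2.39e-05; adjusted p = 0.0849 with an estimated correlation), with Ndufa4l2 at 116.7 ± 29.4 against 16.3 ± 4.89 CPM.

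Many genes moved alike at 16 h and at 3 d. Of those called against NW, 1071 rose at both times, where independent lists would share 241.2, and 743 fell at both, where 152.9 would be shared. At a 2-fold change or more the total went from 1814 to 1365. Both comparisons used the same NW libraries, and 3 of these cannot be divided into separate controls of a size that can be tested, so part of the excess may come from shared controls. In 40 simulations with unchanged wound groups and the same NW libraries the mean and the highest overlap were 0 by edgeR. That simulation leaves out any wound effect, so it does not show how shared controls add to the overlap of lists with real changes. Only 42 genes were called in opposite directions. Of these 38 were lower at 16 h and higher at 3 d, among them P4ha2, Sfrp2 (at 3 d adjusted p = 0.0684 with the keratinocyte covariate) and Fap, the fibroblast activation protein, and 4 the reverse, among them Il31ra.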

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

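The tests on Krt14 ratios, on the Krt15 ratio and on leukocyte transcripts were chosen only after the results were seen, as were the keratinocyte score as a covariate and its tests on chemokine genes at 1.5 d and 3 d; what it should show for chemokine genes at 16 h and immediate early genes at 1.5 d was written down before that was computed. The results here differ between wound times: the change from NW was not the same at 3 d as at 16 h by the direct edgeR test of 3 d against 16 h, or by camera for the lists. That test found 873 genes higher and 547 lower at 3 d. The list medians, 3 d minus 16 h on the log2 scale, were -0.94 for chemokines and cytokines, -0.42 for NF-kB targets, 0.46 for interferon-stimulated genes, 0.50 for glycolysis, 0.65 for hypoxia-responsive genes, -0.87 for cholesterol synthesis, -0.57 for NRF2 antioxidant genes, -1.17 for ribosome biogenesis, 0.72 for G1/S, 2.21 for G2/M, 1.79 for collagens, 0.99 for matrix glycoproteins, 1.38 for collagen processing, 1.66 for contractile genes, 0.81 for Wnt pathway genes, -1.44 for neutrophil markers, -0.64 for keratinocyte markers and 2.15 for pericyte markers. With an estimated correlation only the calls for ribosome biogenesis and contractile genes held. With total-count scaling the median log2 difference of all genes in this comparison was -0.189, against -0.0195 with TMM.

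Among the genes named by the rule, 13 were called in opposite directions from NW at both times. The log2 differences, 3 d minus 16 h, were -1.73 for the vasodilator peptide gene Adm, -2.89 for Aldh1a3, -4.15 for Il31ra, 3.08 for P4ha2, 5.27 for Sfrp2, 5.14 for Lrrc17, 3.25 for Birc5, 8.78 for H19, 2.83 for Fap, 3.16 for Ccnb2, 3.57 for Wnt9a, 2.88 for Col5a1 and 3.38 for Tgfb3. The call of Sfrp2 against NW at 3 d was lost with the keratinocyte covariate (adjusted p = 0.0684), and that of Birc5 at 16 h with the covariate (adjusted p = 0.063) and without replicate 2 of 16 h (0.0605).

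For 3 libraries against 3 there are 10 splits, too few for a share under 0.05, and in each comparison 1 of the 10, the real one, gave as many genes. The real numbers were 3687 at 16 h, 3647 at 1.5 d and 3147 at 3 d against NW, 426 for 1.5 d against 16 h, 21 for 3 d against 1.5 d and 1420 for 3 d against 16 h; the highest other split gave 1 gene for 16 h against NW and no genes by edgeR for the others. For any difference among the 4 groups, 1 of 100 splits, the real one with 4431 genes, gave as many. That is the smallest share this draw could give. The other splits had a median of 0 genes, but the highest gave 2256, 1771 and 1305. This argues against chance as the source of the real count but does not exclude it.

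Keratinocyte markers were lower in wound libraries. The stated gate used CD45, CD31 and SCA1 and named no epithelial marker, so it need not have excluded keratinocytes. A smaller number of keratinocytes in the wound sorts is argued against as the whole cause, since 10 of 17 other markers had a ratio to Krt14 outside the NW range in all 9 wound libraries, 9 below and 1 above. A change in the kind or state of the keratinocytes sorted may take part: the Krt15 to Krt14 ratio lay outside the NW range in 9 of 9 wound libraries, at 2.69% to 12% against 66.9% to 80.6%. This ratio is among the 10 of 17 above and was chosen after it was seen, so it adds no separate support. All 17 ratios also share Krt14 as denominator and are not independent. The Krt14 test replaced an earlier one, also chosen after the data were seen, which found 4 of 18 markers over 2 SE from the list median at 16 h and could not decide by its bounds of 1 and 5. A change in the share in addition to a change in state stays open.

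Chemokine and cytokine genes were higher in wound libraries, where leukocytes gather in the tissue. Leukocytes that passed the CD45 gate are argued against as the source: S100a8, S100a9, Lyz2, Tyrobp and Fcer1g together reached at most 0.57% of the rise of the called chemokine genes in any wound library, the highest sum being 44.67 CPM. A different share of keratinocytes is argued against at 16 h, as 88.9% of the list's calls (16 of 18) were kept with the covariate, against 51.5% over all genes, and the median of the called genes went from 2.21 (SE 0.354) to 2.16 (SE 0.407). At 1.5 d and 3 d 52.9% (9 of 17) and 61.5% (8 of 13) were kept, against 16.4% and 24.6% over all genes. These shares lie between the bounds and do not decide. The medians of the called genes went from 2.28 (SE 0.35) to 2.30 (SE 0.484) and from 2.59 (SE 0.432) to 2.38 (SE 0.509). All 17 and all 13 kept their direction, so calls ended mainly through larger errors. A keratinocyte share as the whole cause should shrink these folds, so the values argue against it for the called genes. This reading of the folds was not part of the bounds. The score runs with the groups, so the reading holds only as far as the fit can separate them. The changes of Il6 and Cxcl1 at 1.5 d did shrink, and a part played by the share stays open. At 16 h a response of the fibroblasts themselves to wounding may underlie the rise, a hypothesis found and tested on the same data, and whether cells of another composition were sorted was not tested beyond these lists.

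Immediate early genes were lower in wound libraries, and such genes respond to tissue dissociation. Less dissociation stress in the wound samples is a candidate explanation: the heat shock members, which stress should move with the rest, had a median at 1.5 d of -1.99 against -1.26 for the other members, a gap of -0.73 within the spread of 1.59, though these members ranged from -2.40 to 0.47 and include the near-identical Hspa1a and Hspa1b. The heat shock members belong to the list whose fall is to be explained, and a biological fall could lower them as well. This result therefore does not favour dissociation stress over such a fall. With the keratinocyte covariate 29.4% of the list's calls at 1.5 d (5 of 17) were kept, under the bound set beforehand for a keratinocyte share as the cause, but so were calls over all genes (16.4% kept), so that bound does not separate this list from others. A further condition, that the fold must shrink as much, was added after this was seen. The median of the called genes went from -1.34 (SE 0.289) to -1.15 (SE 0.339) with 17 of 17 in the same direction, so calls ended through a slightly smaller fold and a larger error, and a keratinocyte share cannot be told apart from the group because score and group run together; a biological fall in the wound stays open and was not tested.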

How the results depend on the processing

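The keratinocyte score as a covariate and the removal of genes that follow it were chosen after the data were seen; the other alternatives were fixed before. Of 304 named-gene results past the threshold, 243 kept their call in every alternative in which they were tested. The other 61 lost it in at least 1, 36 of them without a library. Apart from the panel, these genes were picked from the same fit by size of change or p, so their share does not stand for all calls. Over all genes called against NW, the keratinocyte covariate kept 51.5% at 16 h, 16.4% at 1.5 d and 24.6% at 3 d. Among 428 named results 0 reversed direction where the gene passed the threshold in the main or the alternative fit. Changes of sign in results that passed in neither fit were not counted. DESeq2 size factors left every count of genes within 1.5 times that with TMM. The 722 genes that follow the keratinocyte score were left out without a new fit, so the other genes kept their adjusted p. This says nothing on the calls that remain, and the F test among groups was not run this way. Against NW, falls went from 1672 to 1453 at 16 h, 1613 to 1193 at 1.5 d and 1363 to 1034 at 3 d. Rises went from 2015 to 2003, 2034 to 2024 and 1784 to 1770, so the genes left out were mostly falls. For 3 d against 1.5 d the count of genes depended on several choices; the cause was not tested unless named.

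Total counts as library size gave 30 lower genes for 3 d against 1.5 d and 971 for 3 d against 16 h; the medians over all genes, -0.0941 and -0.189 against 0.0039 and -0.0195 with TMM, moved in that direction. No filter gave 28 higher and 23 lower genes for 3 d against 1.5 d. The filter of 5 CPM in 3 libraries, with 10860 genes tested, gave 26 and 16 there and 109 lower genes for 1.5 d against 16 h. With limma-voom 3 d against 1.5 d gave 52 and 22. DESeq2 gave 124 and 76 there, 835 and 357 for 1.5 d against 16 h, and 1455 and 897 for 3 d against 16 h. With only the 6 libraries compared, and so fewer to estimate the spread, 3 genes were lower in 3 d against 1.5 d.

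The replicate block gave 193 higher and 18 lower genes for 1.5 d against 16 h and 333 lower genes for 3 d against 16 h. The replicate numbers do not pair the libraries: residuals of libraries with the same number correlated at -0.172 to 0.168 with a mean of -0.0193. Only 2 of 12 libraries correlated best with their own number. Other pairs had a mean of 0.0097, but deviations from a group mean cancel out, so that value largely follows from the first and is no separate reference. The block therefore mainly uses up degrees of freedom.

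The keratinocyte covariate gave 1151 higher and 788 lower genes at 16 h, 440 and 175 at 1.5 d and 603 and 196 at 3 d against NW, 225 and 35 for 1.5 d against 16 h, 18 lower genes for 3 d against 1.5 d, and 1924 genes that differed among groups. The score runs with the groups, so the fit loses precision on group differences as well as removing any keratinocyte signal, and these were not separated.

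Of 118 gene list calls 4 held with an estimated correlation; fry made 101 calls, the block 118 and the covariate 109.

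Leaving out 1 library at a time, which leaves a group of 2, gave 1308 to 1855 higher and 941 to 1323 lower genes at 16 h (lowest without replicate 2 of 16 h), 1431 to 1806 and 961 to 1350 at 1.5 d (961 without replicate 3 of 1.5 d) and 1093 to 1643 and 733 to 1125 at 3 d against NW (1093 and 733 without replicate 1 of 3 d, 861 lower without replicate 2 of NW). For 1.5 d against 16 h it gave 137 to 252 and 10 to 44: 164 and 11, 137 and 10, and 196 and 35 without replicates 1, 2 and 3 of 16 h, 227 and 36 and 202 and 16 without replicates 1 and 3 of 1.5 d, and 44 lower without replicate 2 of 1.5 d. For 3 d against 1.5 d it gave 2 to 15 and 0 to 14 by edgeR: 8 and 3 without replicate 1 of 1.5 d, 14 lower without replicate 2, 2 higher without replicate 3, 8 higher without replicate 1 of 3 d, 2 and 0 without replicate 2 (773 genes at an unadjusted p under 0.05; other tools were run only with all libraries, limma-voom giving 52 and 22 and DESeq2 124 and 76) and 2 lower without replicate 3. For 3 d against 16 h it gave 523 to 716 and 203 to 331: 288 lower without replicate 1 of 16 h, 523 and 203 without replicate 2, 331 lower without replicate 3, 549 and 268 and 554 and 258 without replicates 1 and 2 of 3 d, and 323 lower without replicate 3. Any difference among groups was called for 3348 to 4323 genes.

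The self-test recovered at most 11% of genes changed 2-fold and 57% of those changed 4-fold, so a gene that was not called is not shown to be unchanged.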

Other observations

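No test in this part was chosen after its result was seen, since it gives values only. Libraries with at least 1 count for a gene held 14980 ± 190 such genes in NW, 15170 ± 603 at 16 h, 16020 ± 579 at 1.5 d and 16470 ± 137 at 3 d (SD, n = 3). The share of counts on Rn45s, the precursor of ribosomal RNA, was 0.523% ± 0.0329 in NW, 1.28% ± 0.723 at 16 h, 0.713% ± 0.354 at 1.5 d and 0.530% ± 0.182 at 3 d.

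The summed CPM of pericyte and vascular smooth muscle markers ranged from 323 to 379 CPM in NW, 52.7 to 75.9 at 16 h, 77.8 to 96.6 at 1.5 d and 161 to 232 at 3 d. Of this sum Ndufa4l2 alone gave a mean of 237.9 CPM in NW, 17.07 at 16 h, 33.63 at 1.5 d and 111 at 3 d, all before TMM scaling.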
